A study of Pelophylax nigromaculatus with 2 samples.

How the data were processed

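Skin RNA from the black-spotted pond frog, Pelophylax nigromaculatus, was measured by RNA sequencing in 2 libraries, 1 from a non-irradiated and 1 from an irradiated sample. The dose given for the irradiated sample is 30 Gy. Per the labels' protocols, skin was snap-frozen, RNA was extracted with Trizol, and libraries were made from 1.5 μg of RNA with the NEBNext Ultra kit for Illumina sequencing. How many animals gave each sample and how long after exposure the skin was taken are not given in the sources used here.

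For each library the authors deposited an estimated count of reads, not scaled to depth, for each of the same 87406 gene IDs. Per the file headers they also deposited FPKM, which scales the fragments of an ID to its length and to the library total. The count is an estimated count, because only 64.0% of IDs in the non-irradiated and 62.8% in the irradiated library held a whole number (tolerance 0.005). IDs with a value of 0 are included there as whole, so the share among IDs with reads was lower. Fractional values can arise when a read matches several sequences and is divided among them, so counts of near-identical IDs are uncertain. The aligner, the counting program, the assembly and any annotation are not given in the sources used here. The IDs have the form Cluster-number.number and are not paired with gene names in these tables, so 16 gene lists fixed beforehand (among them DNA damage, keratins and muscle) were not run. No coordinates were given or used. No reference genome or annotation was used here.

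The estimated counts were rounded to whole numbers. Of the 8122 IDs with at least 10 reads in all and 0 in one library, 174 had a deposited value above 0 there that rounded to 0. The rounded totals were 16607797 reads in the non-irradiated and 15172889 in the irradiated library. Effective library sizes were set with the TMM method of edgeR 4.0.16 in R 4.3.3. The factors were 0.913 for the non-irradiated and 1.10 for the irradiated library, which moved every log2 ratio by -0.26 against scaling to the total. Ratios were normalized reads in the irradiated over the non-irradiated library. An exact 95% Clopper-Pearson interval of each ID's split of reads was computed with scipy 1.17.1. The intervals and floors cover counting error only. Reads were not counted by molecule, so they are not independent molecules.

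The design has 1 library per group and no replicate. No test of the condition was possible, no p-value across genes is reported, and a ratio compares these 2 libraries. The rule for calling an ID higher or lower was set before the data were examined. It required at least 10 reads over both libraries and a whole interval beyond a 2-fold ratio. An ID with at least 10 reads in one library and 0 in the other met the rule by construction. A count of 0 was set at a floor of 3 reads per library, so its fold is a lower bound at that floor only. The exact interval of such an ID can start nearer to no change. Medians of log2 ratios use that floor. The named IDs were the 2 in each direction, among IDs with at least 100 reads, whose interval bound nearest to no change lay farthest from it.

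The length of an ID was implied by its count and FPKM and the library total, in the library with more reads. It rests on the assumption that the FPKM values were scaled to these totals. The implied length was longer in the non-irradiated library by a near-constant 5.75 bases (median), as for an effective length reduced by the fragment size. The length classes are therefore of implied length and not of the length of the sequence of an ID. For comparison of detection, the deeper library was thinned without replacement to the total of the shallower one in 20 draws. The labels of the IDs found in one library only were shuffled 1000 times in the test of IDs that share a prefix.

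The rule was tested on simulated data for the comparison of the 2 libraries. Poisson counts were drawn for the real IDs, with 50 IDs changed at each fold size, and 54363 IDs were tested. The rule recovered 32% of planted 3-fold changes, 50% of 4-fold, 86% of 8-fold and 94% of 16-fold changes, and called 9 of 54166 unchanged IDs. The simulated libraries differed only by counting error and the planted changes. The 9 calls therefore give no rate of false calls where animals or preparations differ or reads are shared between IDs. The alternatives tried were the scaling (total, DESeq2 1.42.0 size factors, upper quartile), the filter, the fold limit, FPKM ratios with pseudocounts of 0.1 and 1, sums over IDs with a shared prefix, and an edgeR exact test with an assumed coefficient of variation of 0.4. That test gives adjusted p-values that rest on the assumed spread, so only its number of IDs is given.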

Results

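The skin transcriptome of the frog Pelophylax nigromaculatus was compared between a sample irradiated at 30 Gy and a non-irradiated sample, with 1 library each. The non-irradiated library held 16607797 reads and the irradiated library 15172889 reads over 87406 gene IDs of an assembly. There were no replicates, so every difference reported is between these 2 libraries and has no replicate check. Intervals are exact 95% intervals and cover counting error only. Because the IDs were not paired with gene names, groups of IDs are described by abundance, by length and by the prefix of the ID, and no pathway is named.

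Both skin libraries were dominated by a small set of abundant transcripts, and the sets of the 2 libraries overlapped. The most abundant ID was the same in both and took 3.18% of reads (3.17 to 3.19) without and 3.64% (3.63 to 3.65) with irradiation. The 10 most abundant IDs of each library held 12.2% (12.16 to 12.19) of non-irradiated and 14.4% (14.40 to 14.44) of irradiated reads, and 5 of the 10 were shared. The 100 most abundant held 41.5% (41.48 to 41.53) and 44.0% (44.02 to 44.07), with 74 of 100 shared. The 1000 most abundant held 77.6% (77.55 to 77.59) and 77.2% (77.15 to 77.19). The shares of the 10 and the 100 most abundant IDs were thus higher in the irradiated library, and that of the 1000 most abundant was lower, each by more than counting error. On summed FPKM the share of the 1000 most abundant was the other way round, 87.0% in the non-irradiated and 88.5% in the irradiated library. Ranked by FPKM, 6 of the 10 and 54 of the 100 most abundant IDs were shared.

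The 126 IDs that were among the 100 most abundant in either library included 17 that were higher in the irradiated library, 22 that were lower and 87 that did not pass the rule. Their log2 ratios ran from -3.46 to 3.90. With scaling to the total instead of TMM, 19 were higher and 14 lower, so the balance between directions turned with the scaling. The most abundant ID had a normalized ratio of 0.954 (0.9501 to 0.9573) with TMM and of 1.14 with the total, on opposite sides of no change.

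More IDs carried reads in the irradiated library, although it was the shallower one. At least 1 read was found for 68880 IDs in the irradiated and 67115 in the non-irradiated library, and at least 10 reads for 38826 and 34923. After the non-irradiated library was thinned to the irradiated total, 66628 ± 24.6 IDs (SD over 20 draws) had at least 1 read and 33320 ± 32.04 had at least 10. Reads were present in both libraries for 57416 IDs, in the non-irradiated only for 9699, in the irradiated only for 11464 and in neither for 8827.

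Across all IDs, the Pearson correlation of log2(CPM + 1), where CPM is the count scaled by the library total, between the libraries was 0.847 and the Spearman correlation 0.584. Among the 2587 IDs with at least 1000 reads over both libraries the values were 0.675 and 0.592. These correlations are across genes, which are not independent replicates.

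The comparison of irradiated with non-irradiated skin gave large differences in both directions. Among 54838 IDs with at least 10 reads, 7692 were higher in the irradiated library, 7382 were lower and 39764 did not pass the rule. Of these 15074 called IDs, 8122 had 0 reads in one of the libraries. Among the 46716 IDs with reads in both, 3084 were higher and 3868 lower. Scaling to the total turned that balance, with 4348 higher and 2800 lower. Beyond a 4-fold ratio, 790 IDs with reads in both were higher and 1178 lower. Beyond 32-fold, 27 were higher and 53 lower. With IDs at 0 in one library included, 3299 were higher and 3394 lower beyond 4-fold, and 180 and 229 beyond 32-fold. These larger limits were counted under TMM only, so their balance may also turn with the scaling.

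**Figure D1:**
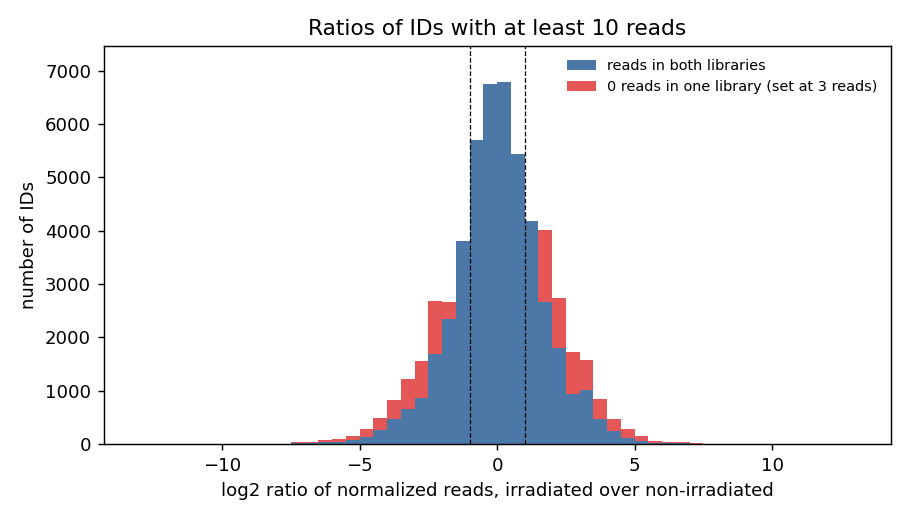
Number of IDs (vertical axis) by log2 ratio of normalized reads in the irradiated over the non-irradiated library (horizontal axis, bins of 0.5) for the 54838 IDs with at least 10 reads. Blue bars are IDs with reads in both libraries, and dashed lines mark a 2-fold ratio. Red bars are the 8122 IDs with 0 reads in one library, whose 0 was set at 3 reads. The red IDs form a shoulder on each side, with an inner edge set by the minimum of 10 reads and the floor of 3 reads.

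The direction differed between abundance classes. Among IDs with 10 to under 100 reads, 6131 were higher in the irradiated library and 5067 lower, with a median log2 ratio of 0.21 (quartiles -1.08 and 1.55). The 7671 IDs of this class with 0 reads in one library all passed the rule by construction. Among its 33790 IDs with reads in both, 1775 were higher and 1752 lower, or 2632 and 1218 with scaling to the total. Among those with 100 to under 1000 reads, 1325 were higher and 1682 lower, with a median of -0.13. With scaling to the total this class turned to 1660 higher and 1300 lower, with a median of 0.13. Among IDs with 1000 to under 10000 reads, 191 were higher and 521 lower, with a median of -0.43. Of the 423 IDs with 10000 reads or more, 45 were higher and 112 lower, with a median of -0.38. In these last classes lower IDs also outnumbered higher ones with scaling to the total, with 249 against 401 and 59 against 80. IDs with 10 to under 100 reads held 3.62% of non-irradiated and 4.61% of irradiated reads, and those with 1000 to under 10000 reads held 20.3% and 18.3%.

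The direction also differed with the length implied by count and FPKM, which may be an effective length shorter than the sequence of the ID. Of 4702 IDs under 100 bases, 437 were higher in the irradiated library and 1202 lower, with a median log2 ratio of -0.72. Of 7163 IDs of 100 to 300 bases, 640 were higher and 1048 lower. Their median was -0.21 with TMM and 0.05 with the total. Of 20650 IDs of 300 to 1000 bases, 2295 were higher and 2231 lower, and scaling to the total gave 2685 and 1885. IDs of 1000 to 2000 bases had 2309 higher and 1758 lower, and IDs of 2000 to 5000 bases 1809 and 1071. Among IDs with at least 1000 reads, lower IDs outnumbered higher ones in both of these length classes, with 40 higher and 82 lower, and 27 and 38. Scaling to the total gave 54 and 55, and 37 and 25. At that abundance the class of 300 to 1000 bases had 54 higher and 187 lower (66 and 138 with the total), and the 34 IDs over 5000 bases had 10 higher and 1 lower. Of the 602 IDs over 5000 bases, 202 were higher and 72 lower, with a median of 0.68. Many calls in the longer classes were IDs at 0 in one library, which passed the rule by construction. They numbered 2528 at 1000 to 2000 bases, 1787 at 2000 to 5000 bases and 160 over 5000 bases. Such IDs were 9.83% of the class under 100 bases and 26.6% of the class over 5000 bases. Among IDs with reads in both libraries, the medians of these 2 classes were -0.71 and 0.52. The Spearman correlation of the log2 ratio with length was 0.136 across the 54838 IDs, and does not depend on the scaling. It was 0.165 within the Cluster-415 prefix, which held most IDs, and 0.0764 outside it.

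**Figure D2:**
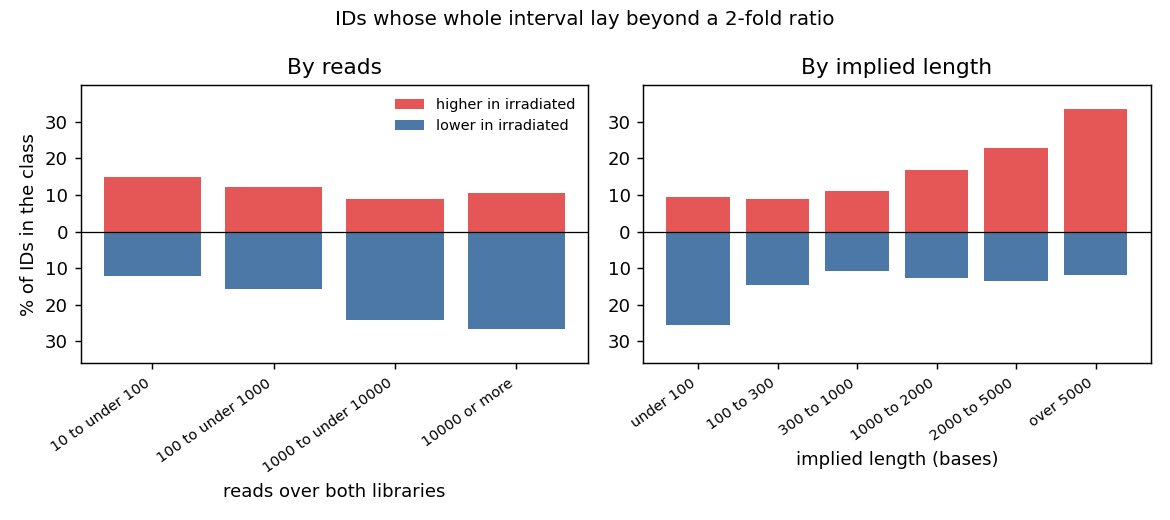
Percent of IDs in each class (vertical axis) whose whole interval lay beyond a 2-fold ratio, above the line for higher and below the line for lower in the irradiated library, by reads over both libraries (left) and by implied length in bases (right). The higher share is 9.29% under 100 bases, 8.93% at 100 to 300 bases and 33.6% over 5000 bases, and the lower share grows from 12.2% at 10 to under 100 reads to 26.5% at 10000 reads or more, under TMM scaling; with scaling to the total the 100 to under 1000 read class changes to more higher than lower IDs.

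IDs outside the largest assembly group took a larger share of reads in the irradiated library. A single prefix, Cluster-415, held 49454 of the 87406 IDs (56.6%) and most reads of both libraries. The other 29072 prefixes took 3.0% (2.99 to 3.01) of non-irradiated and 3.91% (3.90 to 3.92) of irradiated reads. Outside Cluster-415, 3313 IDs were higher and 2329 lower, with a median log2 ratio of 0.28. Scaling to the total gave 3827 and 2055. With TMM factors computed from these IDs alone the counts were 2542 and 2635 and the median 0.08. That setting centres the group by construction, so it cannot test the excess of higher IDs, which is stated relative to the scaling over all IDs. Within Cluster-415, 4379 were higher and 5053 lower, which turned to 5129 and 4259 with scaling to the total.

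A further group of IDs was read in one library only. At least 10 reads in the non-irradiated and 0 in the irradiated library were found for 3514 IDs, which held 0.799% of non-irradiated reads. The reverse was found for 4608 IDs, which held 1.08% of irradiated reads. At equal normalized levels, counting error alone would give 2.75 and 7.42 such IDs. With at least 100 reads there were 199 and 252, and with at least 1000 reads there were 4 and 4. A count of 0 allows up to 3 reads, or 0.181 CPM in the non-irradiated and 0.198 in the irradiated library.

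The named IDs were read almost entirely in one library, and 3 of the 4 had 0 reads in the other. Cluster-415.21545 had 3124 reads in the irradiated and 1 in the non-irradiated library, a ratio of 2850 (511 to 112624). Its FPKM was 261 and 0.11, and its implied length 788 bases. Cluster-415.20673 had 1938 reads in the irradiated library and 0 in the other, so it was at least 589-fold higher at the floor of 3 reads, with an exact interval that starts at 479-fold, and its implied length was 2075 bases. Cluster-415.24660 had 0 reads in the irradiated and 3139 in the non-irradiated library. It was at least 1147-fold lower in the irradiated library at that floor, with an interval that starts at 932-fold and an implied length of 940 bases. Cluster-415.22059 had 0 and 1721 reads, at least 629-fold lower at the floor, with an interval that starts at 511-fold and an implied length of 1165 bases. The deposited counts of Cluster-415.20673, Cluster-415.24660 and Cluster-415.22059 were fractional (1937.53, 3138.95 and 1721.19), as was the count of 1.43 for Cluster-415.21545 in the non-irradiated library, so their reads may have been divided among several IDs.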

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

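With 1 library per group no replicate could be left out, and depth limits what the rule can call: 32% of planted 3-fold changes were recovered in simulated data. The cause of each change below was not tested unless it follows from the setting itself. Alternatives named as outside Cluster-415, as whole counts or as without IDs at 0 were chosen after seeing the data, as was centring within length classes. The counts of 7692 higher and 7382 lower IDs stayed within 1.5 times under total, DESeq2 and upper quartile scaling. The total gave 8956 and 6314, the largest move of these. The counts also stayed within 1.5 times without the 100 most abundant IDs in the totals, without a filter, and centred within length classes. TMM factors computed outside Cluster-415 or on prefix sums were not applied to all IDs. Requiring at least 50 reads gave 2717 and 3355, and an interval beyond 1 gave 15470 and 15463. An interval beyond 4-fold gave 3299 and 3394, and the ratio itself beyond 2-fold gave 16187 and 13975. FPKM ratios gave 13455 higher with a pseudocount of 0.1 and 13930 with a pseudocount of 1 and no filter; the lower counts stayed within 1.5 times, as did both counts with a pseudocount of 1 over 1 FPKM. The edgeR exact test with an assumed coefficient of variation of 0.4 counted 5123 and 4435 at an adjusted threshold of 0.05. Unlike the rule, it asked for any difference and had no 2-fold limit. Without IDs at 0 in either library 3084 and 3868 were left, and with whole counts only 1956 and 1856 (2427 and 1504 with the total). Outside Cluster-415 there were 3313 and 2329 one by one, and 2542 and 2635 with TMM computed there, which centres that group by construction. Summing by prefix gave 2542 and 1760, with or without Cluster-415, which merges into a single entry that was not called. These sums kept the TMM factors of all IDs. TMM on the prefix sums would move log2 ratios by -0.48 against the total, and not by -0.26, so this excess of higher prefixes is relative to the scaling. IDs in the non-irradiated library only (3514) and the irradiated only (4608) became 5806 and 7522 at 5 reads, 1710 and 2221 at 20 reads, 1583 and 2323 outside Cluster-415, 1134 and 1649 summed by prefix, and 776 and 1025 with whole counts. Thinning kept them within 1.5 times, and the irradiated number was the higher in each of these settings. Detected IDs fell by construction to 34923 and 38826 at 10 reads and to 38575 and 45561 at 1 FPKM. The 10 most abundant IDs held 15.6% of non-irradiated and 21.3% of irradiated summed FPKM, and the 100 most abundant 44.7% and 50.8%. By prefix, where Cluster-415 is a single entry, the shares were 97.0% and 96.1% for the first 10 and 97.2% and 96.4% for the first 100. The Pearson correlation was 0.774 on log2(FPKM + 1), 0.726 on log2(CPM + 0.1) and 0.812 with at least 10 reads, and the Spearman correlation was 0.500, unchanged at 0.584, and 0.475.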

Other observations

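The tests of counting error and of the reads left outside the abundant IDs, and the pairs of IDs with reads in both libraries, were set out after the result was seen; the other tests were set out before their result was seen. Outside Cluster-415, pairs of called IDs with reads in both libraries and a shared prefix mostly went the same way. Of 134 such pairs, 11.2% went in opposite directions, against 39.6% to 57.5% in the central 95% of 1000 shuffles of the directions. A prefix with several such IDs adds several pairs, and the number of prefixes behind these pairs was not counted. A few prefixes may therefore carry this result. IDs that share a prefix may also share reads, so these pairs are not independent measurements. Of the pairs of one-library IDs, described next, 54.3% were opposite.

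The 8122 IDs with at least 10 reads in one library and 0 in the other are many more than the 10.2 that counting error would give, which argues against counting error. Among IDs with 10 to under 100 reads, 77.2% (76.2 to 78.1) of the one-library IDs had a fractional count against 51.5% (50.9 to 52.0) of IDs with reads in both, and the smallest such difference over the read classes with enough IDs was 21.9 percentage points. This is consistent with reads being divided between near-identical IDs and going to one of them in each library. Outside Cluster-415, 152 of 280 pairs of one-library IDs with a shared prefix (54.3%), from 191 prefixes, were of opposite libraries. The central 95% of 1000 shuffles ran from 41.8% to 53.9%, and 20 shuffles lay at or above the observed share. This small excess goes with the hypothesis that some loci were split into IDs following the allele or isoform of each library. Reads divided between near-identical IDs could give such pairs too, so the test cannot tell the 2 explanations apart. The pairs cover few of the one-library IDs. For the rest, a response to irradiation, transcripts of another organism and a difference between animals stay open. There are no sequences and no second library per group to decide between them.

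Longer IDs leaned towards the irradiated library. The Spearman correlation with length was 0.219 among the 2587 IDs with at least 1000 reads, which argues against a bias confined to thinly read IDs; among the 423 IDs with 10000 reads or more it was 0.0227, and outside Cluster-415, over all read classes, it was 0.0764. The length implied by count and FPKM was longer in the non-irradiated library by a median of 5.75 bases (quartiles 5.55 and 5.80) over 3833 IDs with at least 200 reads in each, almost the same number of bases for long and short IDs. Among the 46804 IDs with FPKM above 0 in both libraries, the Spearman correlation was 0.139 on counts and 0.126 on FPKM ratios. FPKM carries the implied length of each library, so the 5.75-base difference accounted for little of the trend over all these IDs. It is a larger part of the length of short IDs, and FPKM ratios of the class under 100 bases were not examined separately. Other effects of fragment size, or of RNA integrity, remain candidate explanations. Without read positions along the transcripts they cannot be told apart from a response to irradiation.

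More IDs carried reads in the irradiated library despite its lower depth. It had 1765 more IDs with a read, at 15172889 against 16607797 reads. Whether abundant IDs may have taken reads from the others in the non-irradiated library depended on where abundant began. IDs under 10000 reads over both libraries held 5632338 non-irradiated and 5069602 irradiated reads. IDs under 1000 reads held 2266340 and 2299948 (a difference of -33608), and IDs under 100 reads 656953 and 763187. Without the 1000 most abundant IDs, 3842761 non-irradiated and 3585778 irradiated reads were left. At 3585778 reads each, 67880 irradiated and 65745 non-irradiated IDs (SD over draws 18.3) had a read. The excess remained without these 1000 IDs, which argues against them as its source. For less abundant IDs that explanation stays open. With 1 library per group, irradiation and a difference between animals or preparations cannot be told apart.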
